A study of Homo sapiens with 6 samples.

How the data were processed

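RNA was measured in 6 samples of U266, a human multiple myeloma cell line: 3 control samples and 3 samples transduced with a lentiviral vector that carries MYC behind the EF1A promoter. The sources used here do not say whether the controls carry a vector, so an effect of transduction itself was not separated from that of MYC. Per the labels' protocols, total RNA was extracted with a column kit, poly-A enriched and made into single-barcoded libraries with a kit that does not mark strand, and sequenced on an Illumina instrument. Per the submitters' processing notes, the tools were cutadapt and TopHat2 and the genome build was GRCh37. Their versions, and the gene annotation, are not given in the sources used here. Per the file headers, the authors deposited RSEM gene tables with an expected count, a TPM and an effective length per gene and library. The expected count is an estimate that shares reads between similar genes and need not be whole. Without strand, reads of overlapping and antisense genes were not told apart. The deposited TPM values are scaled by the authors for effective length and depth and sum to the same total in each library. The deposited effective length, in bases, is a value of its own per gene and library and was used only in an alternative.

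Each library's table held 57820 gene rows, and 51996 of these identifiers matched a symbol in a table of gene names, carrying 98.3% of the counts. No row lacked a gene identifier. The 47 second copies of the genes shared by both sex chromosomes held a count of 0. Summed expected counts ran from 27139978 to 158667309 per library, a 5.85-fold range. The shallowest MYC library may thus limit the precision for low genes. Reads without molecular identifiers are not independent molecules, and the spread between libraries rather than a counting interval is the error given throughout.

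Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3: default expression filter, TMM factors, a model with the group only, and the quasi-likelihood F test with Benjamini-Hochberg adjustment over the 17679 genes tested. A gene was called at an adjusted p under 0.05. Values are CPM (counts scaled to a fixed library total) with TMM factors, as mean ± SD over 3 libraries, and log2 fold changes of MYC against control with a standard error (SE) derived from the F statistic. Tested on simulated counts for the 17679 genes of this comparison, with 200 genes changed, the test recovered 58.2% of 1.5-fold, 79.1% of 2-fold and 93.9% of 4-fold changes, and 14 of its 168 calls were unchanged genes.

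The 30 gene lists were written from general knowledge, and the rule for named genes, the tests and most alternative settings were fixed, before the data were examined. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), with camera using an estimated correlation and with fry as checks. The lists had 11 symbols without a match. The lists cover MYC target genes, genes repressed by MYC in other systems, the MYC family and MAX network, glutamine and glutamate metabolism, NAD metabolism, glycolysis, nucleotide and one-carbon synthesis, ribosome biogenesis, cytosolic ribosomal proteins, oxidative phosphorylation, mitochondrially encoded transcripts, polyamines, G1/S, G2/M, plasma cell identity, protein folding in the endoplasmic reticulum, the ATF4 response, interferon-stimulated genes, antigen presentation, p53 targets, the BCL2 family, IL6 and NF-kB signalling, cholesterol and fatty acid synthesis, lysosome and autophagy, markers of B cells, of T and NK cells, of myeloid, of stromal and of epithelial cells, and replication-dependent histones. Genes were named by a fixed rule: MYC, MYCL, MYCN, MAX, NAMPT, GAPDH and ACTB always. A further gene of this part of the rule is not reported here. To these came the 10 largest increases and 10 largest decreases among called protein-coding genes with a proper symbol, mean CPM of at least 5 and no overlap between the groups, and up to 4 called members per list by smallest adjusted p. Where a list had fewer than 2 called members, up to 2 of its most abundant members could be named. All members of the glutamine, NAD and MYC family lists could be named. Other names are said to have been chosen after their values were seen.

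The settings varied were RLE factors, total counts only, DESeq2 1.42.0, limma-voom, limma-trend on log2(TPM + 1) and log2(TPM + 0.1), no expression filter, mean CPM of at least 5, an effective length offset, a replicate block, MYC and the 20 most abundant genes left out, and each library left out in turn. Alternatives added after seeing the data were a GC offset, that offset with a replicate block, a term for MYC libraries 2 and 3, that term with the GC offset, and list tests after the GC offset. The GC offset removes each library's loess trend (span 0.4) of log2 CPM on the GC content of the gene's transcripts. GC content came from GENCODE 29 transcripts matched by identifier and was found for 97.3% of the genes tested. The offset assumes that the average gene at each GC content did not change. The trends seen in these libraries were also added to simulated counts for this comparison. The test without the offset then called 4489 unchanged genes and the test with it called 1. The added trends were of the kind that the offset removes, so this outcome was largely built in. It cannot show whether the offset also removes an effect of MYC that follows GC content. Few genes were changed in the simulation, so the scaling was not tested for a comparison in which most genes change. Gene positions are not printed, because an annotation of the build named by the submitters was not used here. No spike-in control is described in the labels, so a change in total RNA per cell was not measurable, and all values are relative to the library.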

Results

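The data are poly-A RNA-seq of U266, a multiple myeloma cell line, in 3 control samples and 3 samples with lentiviral MYC. The design asks how raised MYC changes the transcriptome of these cells, and the series title names NAMPT as a MYC-linked dependency. Summed expected counts were 55026416, 77933587 and 130576913 in the controls and 27139978, 158667309 and 52816733 in the MYC libraries. The labels do not say whether the samples of a group came from separate cultures. The p-values set the group difference against the spread between these samples. That spread may be only technical, so the p-values may not extend to new cultures. No pair of libraries within a group agreed within sampling noise: chi-square per degree of freedom over genes was 8.74 or higher. The first principal component of log2 CPM, with 79.1% of the variance, separated the groups.

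MYC (ENSG00000136997.10), the introduced transcription factor, rose from 4.20 ± 0.304 CPM in control to 102.6 ± 9.43 CPM in MYC libraries (SD, n = 3 each). The log2 fold change was 4.60 ± 0.10 (SE, adjusted p = 9.71e-08, edgeR quasi-likelihood), and all 3 MYC libraries lay above all 3 controls. Reads of the vector and of the endogenous gene were not told apart. NAMPT (ENSG00000105835.7), the rate-limiting enzyme of NAD salvage, stood at 328.3 ± 28.8 CPM in control and 311.2 ± 18.9 CPM in MYC libraries, with a log2 fold change of -0.08 ± 0.08 (adjusted p = 0.416, edgeR). It did not pass the test. With the GC offset, added after seeing the data, NAMPT was called lower, at -0.29 ± 0.04 (adjusted p = 0.000429, edgeR). Over all alternatives its adjusted p ranged from 0.000429 to 0.765. NAMPT was also called lower on log2(TPM + 1), at -0.31 (adjusted p = 0.0261, limma), and with the effective length offset, at -0.28 (adjusted p = 0.00928, edgeR). No alternative called it higher. Reads of NAMPT and of its processed pseudogene were not told apart.

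**Figure D1:**
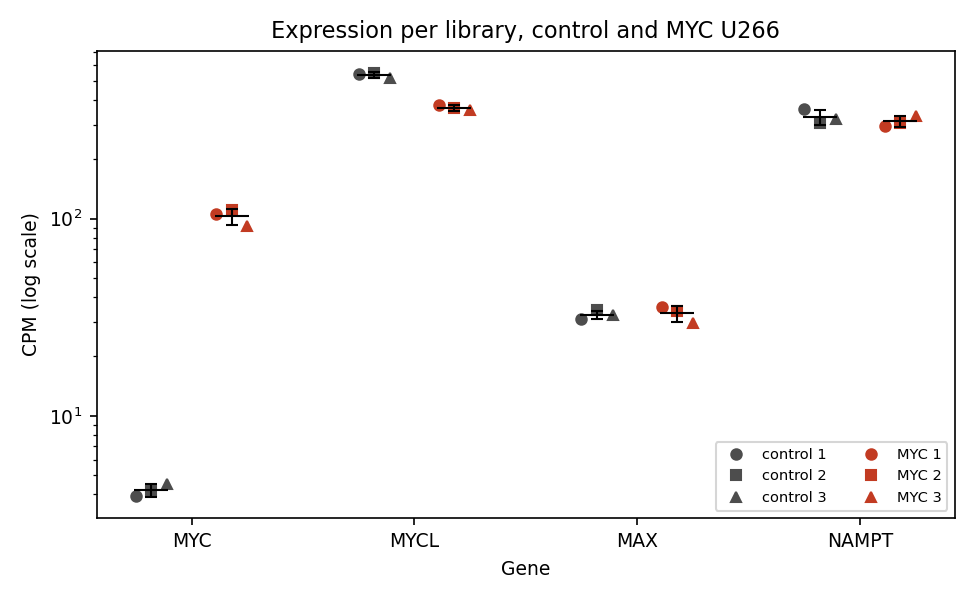
CPM on a log axis of MYC, MYCL, MAX and NAMPT in each library, with controls in grey, MYC libraries in red, a marker shape per replicate number, and the mean and SD of 3 libraries as black bars. MYC lay near 4.20 CPM in controls and 102.6 CPM in MYC libraries, whereas the groups overlapped for NAMPT and MAX.

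Within the MYC family and MAX network, 3 of 11 members tested rose and 6 fell (3 and 6 adjusted over the list alone, camera adjusted p = 0.254). MYCL, the family member most abundant in these cells, went from 534.9 ± 19.1 to 365.2 ± 12.3 CPM, a log2 fold change of -0.55 ± 0.06 (adjusted p = 7.57e-05, edgeR). Its direction turned with the GC offset, to 0.23 ± 0.08 (adjusted p = 0.0309, edgeR), so no direction is given for it. MYCN was near the floor, at 0.568 and 0.383 CPM. Its call (log2 fold change -0.62) ended with the GC offset (-0.24) and without control replicate 2 (-0.64), control replicate 3 (-0.48), MYC replicate 1 (-0.62) or MYC replicate 2 (-0.51). MAX, the partner of MYC in DNA binding, had a log2 fold change of 0.02 ± 0.08 (adjusted p = 0.83, edgeR). The MAX-binding repressor MNT fell 2.82-fold, and 1.56-fold with the GC offset. MXI1 rose 1.53-fold, and 1.44-fold with the offset.

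Across the transcriptome, 5085 of 17679 genes tested were higher and 5671 lower in MYC, and 993 were higher and 2195 lower by at least 2-fold. The groups did not overlap for 67.1% of genes, against 10% by chance. The fold changes followed GC content: the median log2 fold change was 0.26 for genes with 38 to 42% GC and -1.62 for genes over 66% (Spearman's rho -0.55 across genes, which are not independent replicates). All 3 control libraries lay on one side of this trend and all 3 MYC libraries on the other. After the GC offset, 5261 genes were higher and 5108 lower, and at least 2-fold changes were 1112 higher and 867 lower. The share of at least 2-fold changes that were increases moved from 31.1% to 56.2%. Called in the same direction both ways were 3783 higher and 3609 lower genes, and 551 genes were called in opposite directions.

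**Figure D2:**
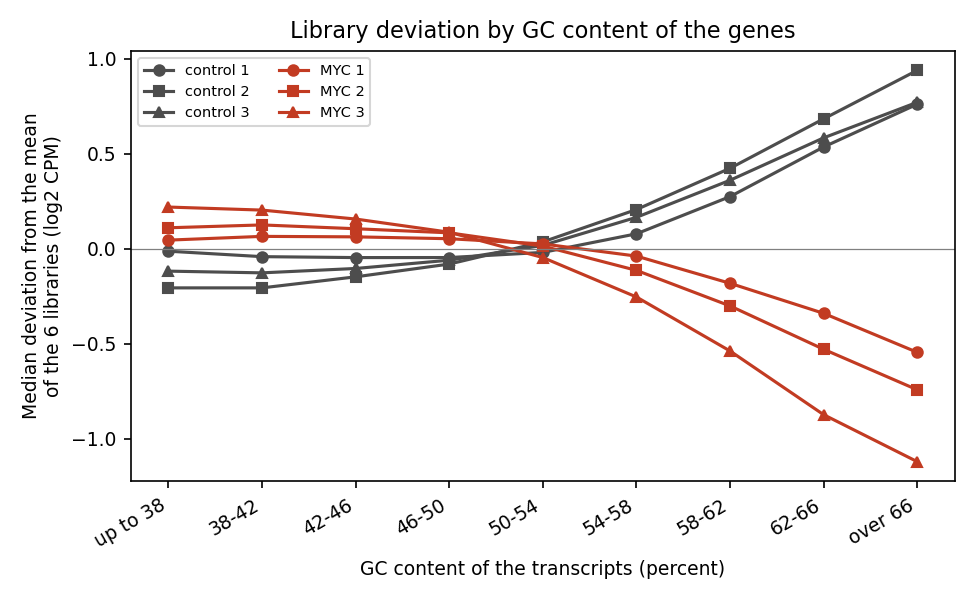
Median deviation of each library from the mean of the 6 libraries, in log2 CPM, over genes grouped by the GC content of their transcripts in percent. Control libraries (grey) rose to between 0.76 and 0.94 for genes over 66% GC and MYC libraries (red) fell to between -0.55 and -1.12.

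The largest increases by the named-gene rule, besides MYC, were genes low in control. PLEK, which encodes pleckstrin, a protein kinase C substrate of blood cells, rose from 2.92 ± 0.18 to 78.7 ± 2.27 CPM (27.1-fold, adjusted p = 2.79e-08, edgeR). TLR7, an endosomal RNA sensor, rose 20.6-fold to 15.5 ± 0.217 CPM, and the tyrosine kinase SYK rose 18.7-fold to 15.6 ± 0.536 CPM. RGPD3, RASGRF1, HBE1, CGA, SKAP1 and MGAT4A rose between 10.7-fold (MGAT4A) and 17.1-fold (RGPD3). RGPD3 shares reads with near-identical copies, so its value is uncertain. All 10 were also called higher with the GC offset, where PLEK was 24.3-fold and MGAT4A 8.96-fold higher.

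Of the 10 largest decreases, all except MGAT2 were smaller once GC content was taken into account. PRSS8, a membrane serine protease, fell from 21.6 ± 0.342 to 1.35 ± 0.42 CPM, 16.6-fold lower (adjusted p = 7.27e-07, edgeR) and 7.70-fold lower with the GC offset. MGAT2, an enzyme of N-glycan synthesis, was 14.6-fold lower, and 16.1-fold lower with the offset. IRF7, a regulator of interferon genes, was 8.99-fold lower and 3.10-fold lower with the offset. MLC1 was 8.89-fold and 6.58-fold lower in the same order, DPM3 8.55-fold and 4.43-fold, and SYTL1 8.26-fold and 3.26-fold. TRAPPC5, NDUFB7, JSRP1 and CHPF were 7.12-fold to 8.04-fold lower, and 2.43-fold to 3.22-fold lower with the offset. All 10 were called lower both ways.

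Of 71 ribosome biogenesis genes, 51 rose and 10 fell (52 and 10 adjusted over the list alone), with a median log2 fold change of 0.44 (camera adjusted p = 8.26e-07, adjusted p = 0.558 with an estimated correlation). POLR1B, a subunit of RNA polymerase I, rose 1.65-fold, HEATR1 1.86-fold, LYAR 1.79-fold and WDR3 1.83-fold. With the GC offset these rose 1.53-fold, 1.58-fold, 1.57-fold and 1.58-fold. Of 78 cytosolic ribosomal proteins, 37 rose and 16 fell (37 and 16 adjusted over the list alone, camera adjusted p = 0.0143, adjusted p = 0.772 with an estimated correlation). RPL7 rose 1.62-fold, RPL6 1.54-fold and RPL5 1.51-fold, and these genes share reads with pseudogenes. The call for ribosomal proteins ended without MYC replicate 1 (camera adjusted p = 0.0922). Of 58 MYC target genes, 27 rose and 14 fell (27 and 14 adjusted over the list alone, camera adjusted p = 0.0375, adjusted p = 0.723 with an estimated correlation), and with the GC offset 44 rose and 6 fell (camera adjusted p = 1.05e-07, adjusted p = 0.202 with an estimated correlation). Without the offset, the call for MYC targets ended with the replicate block (camera adjusted p = 0.0804). It also ended when control replicate 1 (camera adjusted p = 0.0549), control replicate 3 (0.0529) or MYC replicate 1 (0.182) was left out. Among the MYC targets HSPE1, a mitochondrial chaperonin, rose 2.26-fold and PRMT3, an arginine methyltransferase of ribosomal protein, rose 1.82-fold.

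In glycolysis 13 of 24 genes rose and 5 fell (13 and 5 adjusted over the list alone, camera adjusted p = 0.0235, adjusted p = 0.642 with an estimated correlation). HK2, a hexokinase, rose from 9.25 ± 0.577 to 50.3 ± 2.33 CPM (5.43-fold, adjusted p = 2.61e-07, edgeR). The lactate dehydrogenase genes LDHA and LDHB rose 2.06-fold and 1.87-fold. The call for the glycolysis list ended without MYC replicate 1 (camera adjusted p = 0.0922). In nucleotide and one-carbon synthesis 19 of 30 rose and 6 fell (19 and 7 adjusted over the list alone, camera adjusted p = 0.0132, adjusted p = 0.623 with an estimated correlation). PRPS2 rose 1.82-fold and PAICS 1.76-fold, whereas PHGDH, the entry enzyme of serine synthesis, fell 1.85-fold. Of 57 nuclear genes of oxidative phosphorylation, 31 rose and 11 fell (32 and 13 adjusted over the list alone, camera adjusted p = 0.0335, adjusted p = 0.772 with an estimated correlation). This call ended when control replicate 3 (camera adjusted p = 0.0834), MYC replicate 1 (0.124) or MYC replicate 2 (0.057) was left out, and 17 of these genes fell without MYC replicate 1. UQCRC2 rose 1.62-fold, or 1.42-fold with the GC offset, and NDUFS7 fell 4.29-fold, or 1.48-fold with the offset. Of 13 mitochondrially encoded transcripts, 1 was called, MT-ND3 at a log2 fold change of 0.44 (0 adjusted over the list alone, camera adjusted p = 0.254). This call ended with the GC offset (0.18) and without control replicate 1 (0.35), control replicate 2 (0.45) or MYC replicate 2 (0.40), and 6 transcripts were called higher without an expression filter. Of 14 polyamine genes, 8 rose and 4 fell (8 and 4 adjusted over the list alone, camera adjusted p = 0.352), and the median (0.29) and mean (-0.06) differed in sign. Spermine synthase, SMS, rose 2.46-fold and spermine oxidase, SMOX, fell 4.68-fold, or 2.90-fold with the GC offset.

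The glutamine and glutamate genes went both ways: 11 of 33 rose and 13 fell (12 and 14 adjusted over the list alone, camera adjusted p = 0.986). The amino acid transporters SLC3A2, SLC7A5 and SLC1A5 were lower. SLC3A2, the shared heavy chain, fell from 1013 ± 40.5 to 413.8 ± 34.5 CPM (2.45-fold, adjusted p = 4.81e-06, edgeR), SLC7A5 fell 2.66-fold and the glutamine carrier SLC1A5 fell 2.01-fold. After the offset these were 1.71-fold, 1.61-fold and 1.41-fold lower. The transaminase GPT2 fell 2.09-fold (1.61-fold with the offset) and PYCR1 fell 2.94-fold (1.43-fold). Higher in MYC were GOT2 (1.66-fold), ALDH18A1 (1.72-fold), the CTP synthase CTPS1 (1.63-fold), glutamine synthetase GLUL (1.35-fold) and GLUD1 (1.24-fold). The call for GLUL ended on log2(TPM + 1), on log2(TPM + 0.1) and with the effective length offset (log2 fold changes of 0.28, 0.29 and 0.30). In NAD metabolism 8 of 24 rose and 10 fell (9 and 10 adjusted over the list alone, camera adjusted p = 0.787), with a median of -0.02 and a mean of 0.10 on the log2 scale. CD38, an NAD-consuming surface enzyme, rose from 1.22 ± 0.0199 to 7.004 ± 0.49 CPM (5.76-fold, adjusted p = 7.75e-07, edgeR). IDO1 rose 7.15-fold to 2.45 CPM and PARP1 rose 1.39-fold to 481.2 ± 10.3 CPM. NAPRT, which makes NAD from nicotinic acid, fell 5.66-fold from 1.07 CPM (1.76-fold with the GC offset), and SIRT6 fell 4.01-fold (1.56-fold). In cholesterol and fatty acid synthesis 19 of 29 rose and 8 fell (19 and 8 adjusted over the list alone, camera adjusted p = 0.0821), and with the GC offset 20 rose and 3 fell (camera adjusted p = 0.00114, adjusted p = 0.159 with an estimated correlation). The list also passed on log2(TPM + 1) (camera adjusted p = 0.0376). The median was 0.29 and the mean -0.03. ELOVL6 rose 2.01-fold and SCD 1.45-fold, and MVD fell 3.54-fold (1.39-fold with the offset).

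Of 37 G2/M genes, 29 rose and 2 fell (29 and 2 adjusted over the list alone, camera adjusted p = 8.26e-07, adjusted p = 0.558 with an estimated correlation). When a library other than control replicate 1 or MYC replicate 1 was left out, at most 1 fell. KIF20A rose 1.70-fold, BUB1 1.69-fold, BUB1B 1.63-fold and CCNB1 1.62-fold. In the deposited TPM, scaled for effective length, BUB1B rose less, from 60.4 to 69.4. KIF20A went from 27.0 to 44.1 TPM, BUB1 from 72.9 to 119 and CCNB1 from 119 to 190. With the GC offset KIF20A, BUB1B and CCNB1 rose 1.60-fold, 1.40-fold and 1.42-fold, and the list's median log2 fold change moved from 0.475 to 0.328. Of 44 G1/S genes, 27 rose and 6 fell (27 and 8 adjusted over the list alone, camera adjusted p = 0.0024, adjusted p = 0.588 with an estimated correlation). CDK6, a G1 kinase, rose from 11.9 ± 1.11 to 51.9 ± 2.76 CPM (4.36-fold, adjusted p = 7.46e-07, edgeR), UNG and MCM10 rose 1.57-fold each and MCM4 rose 1.46-fold. With the GC offset these were 4.05-fold, 1.53-fold, 1.38-fold and 1.47-fold higher, and the list's median log2 fold change moved from 0.266 to 0.161. Of 13 replication-dependent histones, kept as a sign of RNA quality in poly-A libraries, 10 fell and 0 rose (12 and 0 adjusted over the list alone, camera adjusted p = 0.00144, adjusted p = 0.588 with an estimated correlation). H2AC6 fell 2.35-fold, H2BC21 1.94-fold and H1-4 5.05-fold (3.05-fold with the GC offset).

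Of 27 genes of the ATF4 and amino acid response, 26 fell and 0 rose (27 and 0 adjusted over the list alone), with a median log2 fold change of -0.92 (camera adjusted p = 3.73e-09, adjusted p = 0.399 with an estimated correlation). After the GC offset 24 fell and 0 rose, and this list and the G2/M list passed the test with an estimated correlation (adjusted p = 0.0417 for each). TRIB3, a pseudokinase induced by this response, fell from 346.9 ± 8.26 to 80.2 ± 4.82 CPM, 4.33-fold (adjusted p = 2.43e-07, edgeR), and 1.997-fold with the offset. PPP1R15A fell 4.08-fold (2.97-fold) and ATF5 3.43-fold (1.72-fold). CEBPB fell 2.53-fold, but its direction turned with the GC offset, to a log2 fold change of 0.16 that was not called. In endoplasmic reticulum folding and the unfolded protein response, 8 of 37 rose and 17 fell (9 and 17 adjusted over the list alone, camera adjusted p = 0.24), and with the GC offset 4 rose and 22 fell (camera adjusted p = 0.00236, adjusted p = 0.443 with an estimated correlation). On log2(TPM + 1) 5 rose. The stress sensor ERN1 fell 2.36-fold and SEC61B 1.81-fold, and PDIA3 rose 1.84-fold.

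Among genes repressed by MYC in other systems, 4 of 24 rose and 14 fell (4 and 14 adjusted over the list alone, camera adjusted p = 0.0335, adjusted p = 0.623 with an estimated correlation). The call ended with the GC offset (camera adjusted p = 0.183), with the replicate block (0.069), and without control replicate 1 (0.0623) or MYC replicate 1 (0.0971). With the offset 7 rose and 13 fell, and the median log2 fold change was -0.23, against -0.283 without it. The cell cycle inhibitor CDKN1A fell from 57.96 ± 1.31 to 16.1 ± 1.53 CPM (3.60-fold, adjusted p = 1.04e-06, edgeR), GADD45A fell 3.24-fold and DDIT3 fell 2.03-fold, while CD9 rose 6.83-fold. Of 24 p53 target genes, 9 rose and 13 fell (9 and 13 adjusted over the list alone, camera adjusted p = 0.214), with GDF15 4.30-fold (2.63-fold with the GC offset) and the death receptor TNFRSF10B 1.89-fold lower. After the GC offset 4 rose and 10 fell, and on log2(TPM + 1) 5 rose. Of 17 BCL2 family genes, 1 rose and 10 fell (1 and 10 adjusted over the list alone, camera adjusted p = 0.0335, adjusted p = 0.623 with an estimated correlation), and with the offset 3 rose and 6 fell and the call ended (camera adjusted p = 0.369), as it did without control replicate 1 (0.0623). BBC3 fell 3.89-fold (1.57-fold) and BCL2L12 2.52-fold (1.70-fold). BMF fell 1.503-fold, but its direction turned with the offset, to a log2 fold change of 0.10 that was not called. Of 33 lysosome and autophagy genes, 3 rose and 19 fell (3 and 20 adjusted over the list alone, camera adjusted p = 0.00625, adjusted p = 0.588 with an estimated correlation). Without control replicate 2, control replicate 3 or MYC replicate 2, 1 of these rose, and 5 rose with RLE factors. The autophagy kinase ULK1 fell 5.34-fold (2.28-fold), MAP1LC3B 1.77-fold (2.003-fold), HEXA 1.52-fold (1.54-fold) and the protease CTSD 4.27-fold (1.96-fold), with GC offset values in parentheses.

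Of 24 plasma cell identity genes, 6 rose and 12 fell (7 and 12 adjusted over the list alone, camera adjusted p = 0.254). The surface proteoglycan SDC1 fell from 984.8 ± 54.5 to 436.9 ± 53.8 CPM (2.25-fold, and 1.26-fold with the GC offset), the transcription factor IRF4 fell 1.63-fold (1.81-fold) and DERL3 fell 2.73-fold (1.51-fold). CD38, also on this list, rose 5.76-fold (5.05-fold). Of 40 interferon-stimulated genes, 22 rose and 12 fell (23 and 12 adjusted over the list alone, camera adjusted p = 0.079), with IFIT3 2.92-fold and DDX60 3.76-fold higher and ISG20 5.61-fold lower (3.57-fold with the GC offset). Of 27 antigen presentation genes, 13 rose and 10 fell (13 and 10 adjusted over the list alone, camera adjusted p = 0.182), and with the GC offset 18 rose and 7 fell (camera adjusted p = 0.00202, adjusted p = 0.279 with an estimated correlation). HLA-DRA rose 3.83-fold, HLA-DQA1 6.88-fold, HLA-DRB1 3.31-fold and the protease CTSS 3.09-fold. HLA genes share reads. Of 29 IL6, JAK-STAT3 and NF-kB genes, 6 rose and 16 fell (6 and 16 adjusted over the list alone, camera adjusted p = 0.137), but 15 rose and 7 fell with the offset. IL6R fell 1.55-fold and TYK2 1.98-fold (1.16-fold and 1.13-fold with the offset), and the direction of JUNB turned, from a log2 fold change of -1.12 to 0.20, which was not called.

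**Figure D3:**
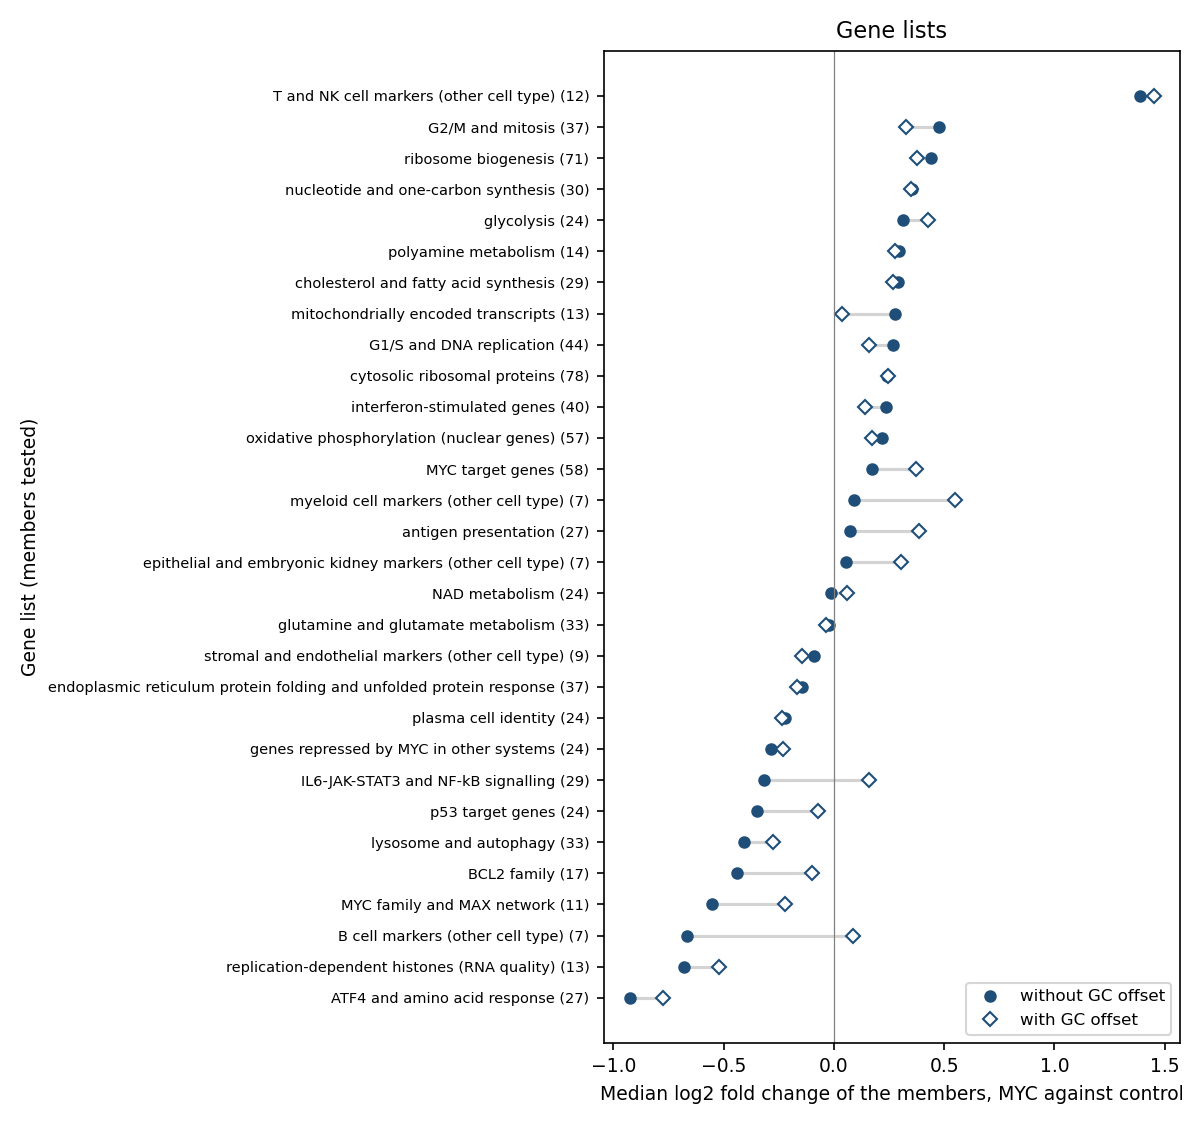
Median log2 fold change (MYC against control) of the members of each of the 30 gene lists, with the number of members tested, without the GC offset (filled circles) and with it (open diamonds). The ATF4 list lay lowest, at -0.92 and -0.78, and the T and NK cell marker list highest, at 1.39 and 1.45.

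Markers of other cell types were measured in the same way. Of 12 T and NK cell markers tested, 9 rose and 2 fell (9 and 2 adjusted over the list alone, camera adjusted p = 0.00571, adjusted p = 0.399 with an estimated correlation), at low levels: GNLY reached 1.502 ± 0.157 CPM, CD3G 2.503 ± 0.307 and CD247 3.17 ± 0.272. When any library other than control replicate 1 was left out, 1 of these fell. Of 7 B cell markers, 3 rose and 3 fell (3 and 3 adjusted over the list alone, camera adjusted p = 0.984), with a median of -0.66 and a mean of 0.05. PAX5 rose 4.61-fold to 2.002 CPM, CIITA rose 1.72-fold and BLK fell 2.39-fold (1.51-fold with the GC offset). Of 7 myeloid markers, 3 rose and 2 fell (3 and 2 adjusted over the list alone, camera adjusted p = 0.53). FCER1G rose from 3.24 to 5.73 CPM and CSF3R fell from 1.68 to 0.169 CPM. Without control replicate 1 or MYC replicate 1, 5 myeloid markers rose. Of 9 stromal and endothelial markers, 3 rose and 4 fell (3 and 4 adjusted over the list alone, camera adjusted p = 0.748), with COL1A1 2.80-fold (1.502-fold with the GC offset) and SPARC 1.83-fold lower. Of 7 epithelial and embryonic kidney markers, 2 rose and 0 fell (2 and 0 adjusted over the list alone, camera adjusted p = 0.276): PEG10 1.79-fold and KRT18 2.21-fold. Of the 30 lists, 14 passed the camera test and 0 passed with an estimated correlation (2 at an unadjusted p under 0.05). With fry, which asks whether the members move one way and does not compare them with other genes, 22 passed, and with camera after the GC offset 15. Without MYC replicate 1, 9 lists passed. The baseline genes did not pass the test, with log2 fold changes of -0.14 for GAPDH and 0.13 for ACTB, but both were called higher with the GC offset (0.24 and 0.80), and ACTB also without MYC replicate 3 (0.27), on log2(TPM + 1) (0.44), on log2(TPM + 0.1) (0.44) and with the effective length offset (0.47).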

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

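The GC offset, the term for MYC libraries 2 and 3 and their combinations were chosen after seeing the data. Across 127 named genes and 21 alternatives, most values kept their direction and side of the threshold. Of the pairs of gene and setting, 2585 kept both, 26 were no longer called, 13 were newly called and 22 had the opposite sign. Most of these genes were named for a large fold or a small adjusted p in the unaltered test, so this stability was partly built in. Over all genes tested, 2813 calls of that test ended with the GC offset, and 551 became calls in the opposite direction. The log2 fold change of MYC ranged from 4.15 on log2(TPM + 1) to 5.16 with the replicate block and GC offset, and from 4.535 to 4.675 with a library left out. MYC and GAPDH have no value where MYC and the 20 most abundant genes were left out. The cause of the changes below was not tested, except that stricter and looser filters test fewer and more genes and that the term for 2 MYC libraries leaves 1 MYC library against the controls, assumed to vary like the others.

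On log2(TPM + 1), 285 genes were higher and 1043 lower by at least 2-fold. Without an expression filter 1573 were higher by at least 2-fold. With mean CPM of at least 5, 3694 genes were lower, 160 higher by at least 2-fold and 996 lower by at least 2-fold. With the GC offset 867 genes were lower by at least 2-fold, and 870 with the replicate block and GC offset. With the term for MYC libraries 2 and 3, 3318 genes were higher and 3682 lower. With that term and the GC offset 3316 were lower and 717 lower by at least 2-fold. With a library left out, higher genes numbered 4184 to 5076, lower genes 4925 to 5809, and those by at least 2-fold 983 to 1140 higher and 2052 to 2561 lower. Lists passing the test numbered 0 with an estimated correlation, 22 with fry, 2 with the GC offset and an estimated correlation, and 9 to 14 with a library left out (9 without MYC replicate 1).

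NAMPT was -0.31 on log2(TPM + 1), -0.31 on log2(TPM + 0.1), -0.28 with the effective length offset, -0.29 with the GC offset, -0.29 with the replicate block and GC offset, -0.32 with the term and GC offset, and -0.141 to -0.0283 with a library left out. MAX was -0.26 on log2(TPM + 1), -0.26 on log2(TPM + 0.1), -0.24 with the effective length offset and -0.034 to 0.0998 with a library left out.

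With the GC offset the sign turned for MYCL (0.23), GAPDH (0.24), CEBPB (0.16), BMF (0.10) and JUNB (0.20). With the replicate block and GC offset these were 0.22, 0.24, 0.14, 0.10 and 0.20. With the term for MYC libraries 2 and 3, GAPDH was 0.0393. With that term and the GC offset MYCL was 0.0877, GAPDH 0.31, MT-ND3 -0.10, BMF 0.0167 and JUNB 0.0494, and the calls for NAPRT, BBC3 and COL1A1 ended. The sample numbers gave no sign of pairing: deviations of same-numbered libraries correlated at -0.05, 0.08 and 0.11. Other pairs ran from -0.164 to 0.103. With 3 libraries per group this cannot exclude a pairing. The replicate block gave 4649 higher and 5380 lower genes, and 9890 of its 10029 calls were shared with the 10756 without it. The list calls for MYC targets (camera adjusted p = 0.0804) and for genes repressed by MYC (0.069) ended with it. The shallowest library, MYC replicate 1 with 27139978 counts, may limit the calls for low genes. Without it 18524 genes were tested, against 17679 with all libraries, and 1140 were higher and 2561 lower by at least 2-fold. Without control replicate 1, a deeper library, 18584 were tested. Leaving out a library also leaves fewer in its group, so an effect of depth alone was not tested.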

Other observations

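Tests in this part were chosen after the result was seen, except the count over other splits of the libraries and the search for sequence shared by the variable genes. Genes named here for the first time were chosen after their values were seen. Within the antigen presentation list, 10 of the 11 genes of the MHC class II pathway rose and 0 fell (median log2 fold change 1.47), and with the GC offset 11 rose. Besides HLA genes these 11 include CIITA, CD74 and CTSS. Of the 16 class I and peptide loading genes, 3 rose and 10 fell, but 7 rose and 7 fell with the GC offset. IGHE, the heavy chain of the antibody that U266 makes, fell from 2931 ± 248 to 707.2 ± 269 CPM (4.15-fold, and 2.07-fold with the offset). The chemokine receptors CCR7 and CCR4 rose from 0.296 to 7.66 and from 0.0962 to 6.23 CPM, and the signalling adaptor PIK3AP1 from 0.119 to 7.77 CPM.

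The comparison called 10756 genes with edgeR, and the highest of the other splits of the 6 libraries into 3 and 3 called 0 (at most 287 at an unadjusted p under 0.05, and at most 3 with DESeq2). Of the 10 splits, 1 gave as many calls, the real split, and 10 are too few for a share under 0.05. Every other split mixes control and MYC libraries, so the difference between the groups widens its spread and few calls follow whatever the cause.

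Fold changes fell with GC content, and a technical bias or an effect of MYC on GC-rich transcripts could each give that. The ribosomal protein genes, made for 1 particle, followed GC content too (rho -0.814 across 78 genes, and -0.47 after the offset, which thus left part of this trend), in line with a bias of library preparation or sequencing, although an effect of MYC on GC-rich transcripts may give the same. The contrast between GC-rich and GC-poor genes spread over 0.675 log2 units among the MYC libraries and 0.317 among controls. This narrowly met a bound, written after the trend was seen, against a shared effect of MYC, which is left open because 3 libraries per group are too few to compare spreads (variance ratio 4.61), a point raised after the values were seen. Because every MYC library lies on one side, the design confounds the trend with the groups, and bias and biology cannot be told apart.

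Immunoglobulin genes split MYC libraries 2 and 3 from the other 4: IGHG1 stood at 19.6 to 23.9 CPM in these 4 and at 3.65 and 4.06 in the pair, while IGHG3 went from at most 0.605 to 13.6 and 10.8. IGLV3-1 and IGLV2-14 traded places in the same way but share 0 25-mers, which argues against reads passing from one of them to the other. Sequence shared with other variable genes was not searched for, so reads from those genes stay open. IGHG1 and IGHG3 share 1524 25-mers, and their sum changed 0.715-fold, so shared reads stay open for that pair. IGHV3-21, a variable gene, split the libraries too, at 1.39 to 1.8 CPM in the other 4 and at 0.0257 and 0.0552 in MYC libraries 2 and 3. MRPL30, a gene outside the immunoglobulin loci, split the libraries as well. It stood at 0.416 to 3.91 CPM in the other 4 and at 27.2 and 53.3 in MYC libraries 2 and 3. It is among the 9 other genes counted below. Reads shared between IGHG1 and IGHG3 do not account for IGHV3-21, IGLV3-1 or MRPL30. IGHG1 in MYC library 1 stood at 1.12 times the control mean, which restates the split, so reads carried over from other libraries of a run stay open. A small share of another plasma cell clone stays open: 9 other genes met a 5-fold bound between these sets, some of them low in MYC library 1 as well and so following the groups, against up to 20 in other splits, and these immunoglobulin genes reached at most 2.58% of IGHE in a library, so a clone of that share would move 5-fold only genes far higher in it than in U266 (a point raised after the count was seen).

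A set of 38 genes, PLEK not among them, was over 8-fold higher in MYC. Its group means were under 2 CPM in controls and 5 CPM or more in MYC libraries. Of these genes, 34 met both levels in every library, and IGHG3, MRPL30, TNFRSF1B and EFNB2 did not. In MYC library 1, IGHG3 stood at 0.605 CPM and MRPL30 at 0.492 CPM, close to the controls. With the GC offset 100% of the 38 genes kept a called log2 fold change of at least 2. The choice of genes over 8-fold higher largely fixed this outcome, because the median log2 fold change was at most 0.26 at any GC content. The GC trend of the average gene is thus too small to give this set, but a GC bias particular to these genes was not tested. Blood cells of another lineage would bring their abundant transcripts, but the highest of 9 of these, LYZ, had a mean of 0.206 CPM in MYC libraries. The median for the set was 7.502 CPM, which argues against cells rich in these 9 transcripts as the source of the whole set. Cells that lack these 9 would go unseen, and the 9 were chosen after the set was seen. Some markers of other lineages did rise, although controls already held them. CD3G went from 0.520 to 2.503 CPM, FCER1G from 3.24 to 5.73 CPM and CD247 from 1.11 to 2.90 TPM. The myeloid marker CSF3R fell from 1.68 to 0.169 CPM, and of the myeloid markers 3 rose and 2 fell. A source of the markers that rose stays open. No other technical explanation was tested for this set, and an effect of the raised MYC was not tested apart from the group comparison.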
